A study of Homo sapiens with 24 samples.

How the data were processed

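Total RNA was measured in 24 libraries from 3 human hepatocellular carcinoma cell lines, HepG2, SNU398 and SNU475. Each line received 4 treatments: vehicle (Dulbecco's phosphate-buffered saline, DPBS), decitabine (the DNA methyltransferase inhibitor 5-aza-2'-deoxycytidine) at 100 nM daily, GSK-126 (an inhibitor of the histone methyltransferase EZH2) at 500 nM daily, or both drugs. Dosing lasted 3 days. Cells were harvested on day 14 (HepG2 and SNU398) or day 21 (SNU475). Each of the 12 groups had 2 libraries, replicates A and B. The sources used here do not say whether A and B came from separate cultures. If they did not, the p-values measure the spread between libraries and not that between cultures. Per the labels, RNA was extracted with Trizol, treated with DNase I, depleted of ribosomal RNA, made into stranded libraries and sequenced on a NextSeq 500 in single reads of 75 bases.

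The authors aligned reads to hg19 with HISAT2 and assigned them with featureCounts. Versions, the annotation release, the strand setting and the treatment of multiply mapped reads are not given in the sources used here. Both deposited tables hold RPKM, one for genes and one for repeat loci, rounded to 3 decimals. From the steps between values of short genes, the read number behind each value could be recovered. Between 99.9% and 100% of the values checked per library were whole reads within a tolerance of 0.15 reads. The recovered denominators ranged from 32.6 to 60.37, in units of 1e6 reads, of which 57.2% to 69.5% lay in genes. Depth per library is in the results below. Counting intervals cover counting error only.

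The gene table held 63677 genes, of which 20068 were at 0 in every library. Genes with RPKM of at least 0.5 in at least 2 libraries were tested (19377 genes). RPKM was scaled per library by median-of-ratios factors over the 8211 genes with RPKM of at least 1 in every library. These factors ranged from 0.847 to 1.158. Scaled RPKM plus a pseudocount of 0.5 was taken to log2, which draws the changes of genes near 0 towards 0. One linear model with a mean per group was fitted to all 24 libraries in limma (12 residual degrees of freedom) with empirical Bayes moderation, trend and robust options. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over all genes of a comparison, and adjusted p under 0.05 was called. All adjusted p-values below come from limma. Values are scaled RPKM means with the SD of the libraries, and log2 changes carry the standard error of the model. The comparisons were each treatment with DPBS in its line, the combination with decitabine and with GSK-126, the interaction (combination minus decitabine minus GSK-126 plus DPBS on the log2 scale, so that 0 means multiplied effects), and the difference between lines in the effect of the combination. For genes near 0 the pseudocount bends the log2 scale, so multiplied effects can give an interaction other than 0. Changes called at least 2-fold were also counted. A gene whose DPBS libraries were all at 0 has no fold, so none is given for it, and its treated level is given in some cases only.

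For 26 gene lists, limma's camera tested whether members moved against the other genes, with the inter-gene correlation estimated per list and adjustment over the 312 tests. The lists were cancer-testis antigens, germ-cell and meiosis genes, HOX genes, developmental transcription factors, Polycomb components and H3K27 demethylases, DNA methylation machinery, interferon-stimulated genes, innate RNA-sensing and interferon signalling genes, MHC class I antigen presentation, chemokines and cytokines, p53 target genes, proliferation genes, hepatocyte genes, oncofetal and progenitor genes, mesenchymal and stellate/fibroblast genes, epithelial genes, imprinted genes, tumour suppressors silenced in liver cancer, cholesterol synthesis genes, unfolded-protein and integrated stress response genes, immune-cell markers, endothelial markers, replication-dependent histone genes, mitochondrially encoded mRNAs, ribosomal protein genes and abundant small structured RNAs. Another 6 lists were added after the data were seen: hypoxia-responsive, metallothionein, MHC class II, interferon-gamma-type, fibrinogen and acute-phase, and snRNA and snoRNA genes.

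The 4494509 repeat loci left after an exclusion by name were summed per subfamily as RPM (reads in 1e6 reads). They included LINE, SINE, LTR, DNA, satellite and SVA elements. Subfamilies with at least 1 RPM in at least 2 libraries were tested in the same model. The sums were not scaled per library, and the pseudocount was 0.5 RPM. There were 843 such subfamilies, or 585 when only loci outside every gene body were summed. The names left out were those of simple repeats, low-complexity sequence and RNA repeats.

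Genes named below were chosen by a rule: EZH2, DNMT1, DNMT3A, DNMT3B, EED, SUZ12 and UHRF1 always; per comparison, the 5 highest and 3 lowest log2 changes among called genes with separated replicates, at least 1 RPKM in the higher group and a gene name that is not a clone, antisense or small-RNA name; per list and comparison, up to 3 called members with the smallest adjusted p; and the 10 genes with the largest smallest change among those called in all 3 lines. Separation was not asked for interactions or for differences between lines. Repeats were named as the 5 highest and 3 lowest subfamilies, with the top locus of those named for the combination. Comparisons, tests, the 26 lists, this rule and the other settings to be tried were fixed before the data were examined.

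The procedure was tested on simulated data. With 240 genes changed, the model called 58 of 63 genes changed 1.5-fold, 62 of 64 changed 2-fold and 64 of 64 changed 4-fold. It was too liberal: 76 of its 276 calls (27.5%) were unchanged genes, against 23 of 194 (11.9%) with the 8 libraries of one line. Of its 79 calls of at least 2-fold, 11 were unchanged genes. With 6000 genes changed, 334 of 4328 calls (7.7%) were unchanged genes, against 155 of 3581 (4.3%). Of the 199 calls of at least 2-fold, 38 were unchanged genes, or 11 of 172 when the higher group reached 1 RPKM and the replicates were separated. Counts of all called genes therefore hold unchanged genes. They also miss changed ones (4328 calls with 6000 genes changed), so they do not bound the number of changed genes. Counts of at least 2-fold carry neither condition and hold unchanged genes too. Genes named as the highest or lowest of a comparison between treatments meet both. Those named for the size of an interaction or a difference between lines had no separation condition. Those named from a list or for a change in every line had to meet neither. In the repeat test, 18 of 20, 20 of 20 and 20 of 20 subfamilies changed 1.5-fold, 2-fold and 4-fold were called, with 8 of 769 unchanged ones. A list raised 1.3-fold was called with an adjusted p of 3.8e-05, and 0 other lists were called. Simulated genes varied independently, with the same extra spread in every group, so this does not cover lists whose members vary together.

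The settings fixed in advance were pseudocounts of 0.1 and 1, no filter or stricter filters, no scaling, quantile normalization, the 8 libraries of a line alone, the replicate letter as a block, leaving out each library in turn, an additive null for the interaction, the preset correlation of 0.01 for lists, other scalings of repeats and each subfamily without its highest locus. Tests added after the data were seen were limma voom on the recovered reads, repeat loci outside gene bodies, and quantile normalization and a pseudocount of 1 for lists, and list medians with members at 0 in both DPBS libraries held at a floor of 3 reads over the group. Replicate letters did not pair samples across treatments: over 18 pairs of groups in a line, correlations of the replicate differences ranged from -0.12 to 0.24. No 2 replicates looked like copies of 1 library. Software was R 4.3.3, limma 3.58.1, data.table (1.17.8), Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The reference genome at hand was another build and was not used for positions, which are those of the deposited tables (hg19). Levels of Y-linked genes and XIST, and 2 genes that the naming rule picked, are not reported here.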

Results

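Total RNA was profiled in 3 human liver cancer cell lines, HepG2, SNU398 and SNU475, 14 days (HepG2, SNU398) or 21 days (SNU475) into a culture that began with 3 days of dosing. Each line received vehicle (DPBS), decitabine, which traps DNA methyltransferases and lowers DNA methylation, GSK-126, which blocks the histone methyltransferase EZH2, or both drugs. Each of the 12 groups had 2 libraries. The reads behind the RPKM unit, counted in units of 1e6, were 32.6 to 34.41 in HepG2 combination libraries and 43.5 to 51.71 in the other HepG2 libraries, 43.3 to 60.37 in SNU398 and 41.31 to 56.21 in SNU475. Between 25476 and 29896 genes were above 0 per library. Levels below are scaled RPKM and changes are log2, with positions on hg19. The series title names a synergy of both drugs in gene activation, so each drug was compared with DPBS, the combination with decitabine, and the combination with the product of the single effects.

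**Figure D1:**
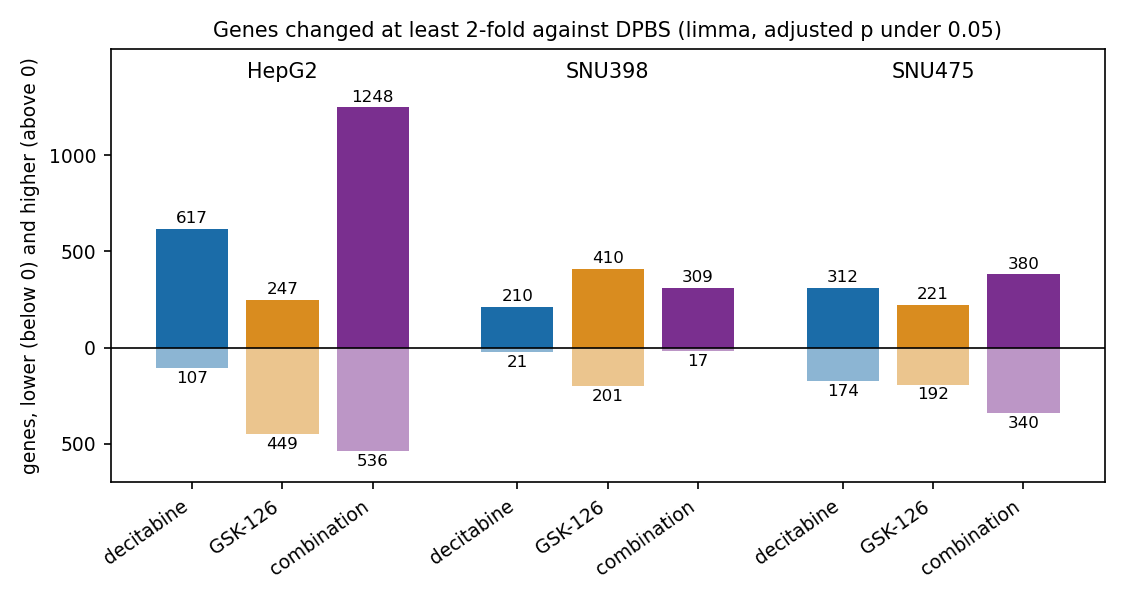
Number of genes called at least 2-fold higher (above 0) or lower (below 0) than DPBS by limma, for 3 treatments (bar colour) in each cell line. The combination gave 1248 higher genes in HepG2, 309 in SNU398 and 380 in SNU475, counts that pseudocounts of 0.1 and 1 and voom moved to between 750 and 3635, 158 and 1873, and 238 and 1081.

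In HepG2, decitabine raised cancer-testis antigens, of which 7 of 23 were listed at 0 in DPBS, germ-cell genes and imprinted genes. With decitabine 617 genes were at least 2-fold higher and 107 lower. Of these, 576 and 104 were also called in a model of the 8 HepG2 libraries alone. Protein-coding genes made up 326 of the 617 and 87 of the 107, and small RNA or other genes 132 and 10. The 2-fold counts depended strongly on the treatment of low values: with pseudocounts of 0.1 and 1 and with voom they ran from 280 to 2555 and 82 to 231. Such ranges follow other 2-fold counts below as low-value ranges. H19, an imprinted long non-coding RNA of fetal liver (ENSG00000130600, chromosome 11, 2016406 to 2022700), went from 1.06 ± 1.2 to 540 ± 21 RPKM (SD, n = 2), a log2 change of 8.69 (SE 0.39, adjusted p 1.4e-10). The lysosomal protease gene CTSZ (ENSG00000101160, chromosome 20, 57570240 to 57582302) rose from 0.0715 ± 0.042 to 15.2 ± 0.06 RPKM (SD, n = 2; log2 change 4.79). GSTP1 (ENSG00000084207, chromosome 11, 67351066 to 67354131), a detoxifying enzyme gene whose promoter is often methylated in liver cancer, rose from 0.0805 ± 0.004 to 7.74 ± 0.67 RPKM (SD, n = 2; log2 change 3.82). Of 23 cancer-testis antigens, which are normally expressed in testis, 21 rose and 0 fell (21 and 0 adjusted over the list alone; median 1.3, adjusted p 0.00024), among them PRAME with a change of 3.13, PAGE1 with 4.02 and MAGEB2 with 3.09. MAGEA4 was listed at 0 in both DPBS libraries. Of 16 germ-cell and meiosis genes 14 rose and 0 fell (15 and 0 adjusted over the list alone; median 0.69), including the piRNA factor gene TDRD12 (1.37). The meiosis gene BRDT was listed at 0 in DPBS and was at 0.614 ± 0.024 RPKM (SD, n = 2). Of 23 imprinted genes 16 rose and 2 fell (17 and 2 adjusted over the list alone; median 0.31, adjusted p 0.0067), including the maternal non-coding RNA MEG3, from 0.0126 ± 0.012 to 4.74 ± 0.044 RPKM (SD, n = 2), and KCNQ1OT1 (1.34). Of 29 p53 target genes 22 rose and 3 fell (23 and 3 adjusted over the list alone; median 0.40, adjusted p 0.043), led by the cell-cycle inhibitor CDKN1A (1.22). Over the 32 proliferation genes 6 rose and 19 fell (6 and 20 adjusted over the list alone; median -0.41, adjusted p 0.0023), with PCNA at -1.07, MCM4 at -0.72 and RRM2 at -0.73, and over the 71 replication-dependent histone genes 13 rose and 46 fell (13 and 46 adjusted over the list alone; median -0.61, adjusted p 0.041). The 3 largest falls were those of the hormone subunit gene INHA (-2.04), the trypanolytic factor gene APOL1 (-1.96) and the hypoxia-induced glycolytic regulator PFKFB4 (-1.91). At any size 10500 genes were called, 66.3% of them higher. That share was 53.3% without scaling and 46.3% after quantile normalization. The p53, proliferation, imprinted and histone calls were lost without scaling, at medians of 0.31, -0.49, 0.26 and -0.69. The proliferation and histone calls were also lost after quantile normalization (-0.42 and -0.56). The p53 call was also lost with a pseudocount of 0.1, with the replicate letter in the model and without any 1 HepG2 library other than DPBS B (adjusted p 0.051 to 0.075), and the histone call without either GSK-126 library or decitabine library B (0.06 to 0.064).

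GSK-126 alone had another profile in HepG2: of the 26 lists fixed in advance, proliferation, histone and cholesterol synthesis genes were called, each lower. The calls of at least 2-fold were 247 higher and 449 lower (233 and 444 also in the 8 HepG2 libraries alone, low-value ranges 144 to 1135 and 349 to 818). MAT2A (ENSG00000168906, chromosome 2, 85766288 to 85772403), the gene of the enzyme that makes S-adenosylmethionine, rose from 16.6 ± 0.023 to 125 ± 0.28 RPKM (SD, n = 2; log2 change 2.88, adjusted p 5.4e-18). The asparagine synthetase gene ASNS rose by 2.74, the cystine transporter gene SLC7A11 by 2.68, the peptide hormone gene ADM2 by 2.64 and the poorly characterised KLHDC7B by 3.10. The 22 unfolded-protein and integrated stress response genes were not called as a list in HepG2. All 32 proliferation genes fell (0 and 32 adjusted over the list alone; median -1.37, adjusted p 8.2e-05), including the replication clamp gene PCNA (-2.36), RRM2 (-2.35) and MCM4 (-1.74). Of the 71 histone genes 3 rose and 52 fell (4 and 53 adjusted over the list alone; median -1.20, adjusted p 0.0099), among them HIST1H2BD (-1.84). Of 24 cholesterol synthesis genes 2 rose and 20 fell (2 and 20 adjusted over the list alone; median -0.83, adjusted p 0.00021), among them FDPS (-1.15) and MSMO1 (-1.56). The largest falls were those of the urea-cycle gene ARG1 (ENSG00000118520, chromosome 6, 131894284 to 131905472), from 11 ± 0.19 to 0.556 ± 0.028 RPKM (SD, n = 2; log2 change -3.45), and of the metal-binding protein genes MT1E (-3.40) and MT2A (-3.17). Cancer-testis antigens stayed near DPBS (median 0.00), as did germ-cell genes. In all 10194 genes were called, 58.8% of them higher.

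The combination produced the broadest activation of any group in HepG2, with 1248 genes at least 2-fold higher and 536 lower (1238 and 526 also in the 8 HepG2 libraries alone, low-value ranges 750 to 3635 and 361 to 898). Of the 1248, 1035 were called above both single treatments, 155 did not differ from decitabine and 29 were below it. The choice of genes by a high combination value favours the first count, and the same holds for such splits in the other lines. PLA2G2A (ENSG00000188257, chromosome 1, 20301925 to 20306932), a secreted phospholipase gene, went from 2.64 ± 0.012 in DPBS to 154 ± 4 RPKM (SD, n = 2; log2 change 5.62), with 37.8 ± 0.35 in decitabine and 0.511 ± 0.11 in GSK-126. CTSZ reached 30.3 ± 0.27 RPKM (log2 change 5.75) and GSTP1 17.4 ± 0.34 RPKM (4.95). H19 reached 807 ± 42 RPKM (9.27) and was not called different from decitabine (0.58, adjusted p 0.23), where voom and leaving out either DPBS library did call it. Of 23 cancer-testis antigens 22 rose and 0 fell (22 and 0 adjusted over the list alone; median 2.17, adjusted p 0.00024), including PAGE1 (4.97), MAGEB2 (4.20) and PRAME (3.78). Of 16 germ-cell genes 14 rose and 0 fell (14 and 0 adjusted over the list alone; median 0.94), including TDRD12 (1.70). Of 38 interferon-stimulated genes 25 rose and 0 fell (25 and 0 adjusted over the list alone; median 0.31, adjusted p 0.018), led by IFI27 (2.16) and IFI6 (2.04). Of 25 chemokines and cytokines 17 rose and 2 fell (18 and 2 adjusted over the list alone; median 0.71, adjusted p 0.013), led by CXCL2 (4.12), IL8 (2.54) and IL18 (2.02), which attract or activate leukocytes. The serine protease inhibitor gene SPINT2 rose by 3.25 and the cell-cycle inhibitor genes CDKN2B by 2.73 and CDKN1A by 1.98. Of the proliferation genes 1 rose and 29 fell (1 and 29 adjusted over the list alone; median -0.67, adjusted p 0.00024), and of the cholesterol genes 7 rose and 15 fell (7 and 15 adjusted over the list alone; median -0.31, adjusted p 0.026). Outside small RNA genes, the lowest were ARG1 (-3.05), the hormone gene EPO (-2.89) and the collagen cross-linking enzyme gene LOX (-2.61). In all 12888 genes were called, 61% of them higher, or 47.9% after quantile normalization. The interferon, proliferation and cholesterol calls were lost without scaling, at medians of 0.27, -0.72 and -0.36. The interferon and cholesterol calls were also lost after quantile normalization (0.13 and -0.32). The interferon call also had an adjusted p of 0.051 with the replicate letter in the model.

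Set against decitabine alone, adding GSK-126 in HepG2 raised 200 genes at least 2-fold and lowered 252, of 10807 called. Low-value ranges were 103 to 1154 and 104 to 556. Small RNA or other genes (1067 tested) made up 17 of the 200 and 131 of the 252. Protein-coding genes (13741 tested) made up 146 and 67. Among the highest were the trypsin inhibitor gene SPINK1 (2.37), PLA2G2A (2.01), the vasoconstrictor gene EDN1 (1.94) and the YAP target CYR61 (1.76), and among the lower genes were the lectin receptor gene CD302 (-1.66) and MSMO1 (-1.64). The interaction asked whether both drugs exceeded the product of their single effects. It was at least 2-fold positive for 601 genes and negative for 735 (low-value ranges 414 to 1149 and 425 to 1350). Most of these genes had an opposite call with a single drug: 503 of the 601 and 556 of the 735 with GSK-126, and 300 and 535 with decitabine. With the combination, 315 of the 601 were called higher than DPBS and 247 of the 735 lower. Protein-coding genes made up 510 of the 601 and 311 of the 735, and small RNA or other genes 13 and 154. A positive value often meant that a fall with 1 drug was absent or smaller with both, as for MT2A (4.27) and PCNA (1.97), and a negative one the same for a rise, as for SLC7A11 (-3.19), ASNS (-2.82) and KLHDC7B (-2.83). MAT2A was at 18.8 ± 0.15 RPKM in the combination. Among the 1248 genes at least 2-fold higher with both drugs, the interaction was positive for 768 and negative for 124, a split that leans positive because these genes were chosen by a high combination value, and over all genes it was positive for 4862 and negative for 5402 (55.6% positive without scaling). Of the 1248, 1076 exceeded the sum of both single gains on the linear scale, a count raised by the same choice and made without a test. Among all 7864 genes called higher it was 5010. Cancer-testis antigens were above the product of effects on the log2 scale (median 0.91, camera, adjusted p 5e-04). Of the members 20 were positive and 0 negative (20 and 0 adjusted over the list alone), including MAGEB2 (1.05, not called by voom) and PRAME (0.73). However, 7 of the 23 members were listed at 0 in DPBS. Near 0 the pseudocount shrinks single effects, so multiplied effects alone can give a positive value for such members. The list interactions were also positive for interferon-stimulated genes (median 0.19, 19 positive and 2 negative, 19 and 3 adjusted over the list alone), germ-cell genes (0.29), proliferation genes (0.97) and histone genes (0.99). Those of the interferon, germ-cell and histone lists were lost without scaling.

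In SNU398, decitabine raised germline genes as in HepG2, together with interferon and antigen-presentation genes. In this line 210 genes were at least 2-fold higher and 21 lower (206 and 16 also in the 8 SNU398 libraries alone, low-value ranges 112 to 1360 and 7 to 84). MYL9 (ENSG00000101335, chromosome 20, 35169887 to 35178228), a myosin light chain gene of contractile cells, rose from 0.196 ± 0.061 to 15.8 ± 0.58 RPKM (SD, n = 2; log2 change 4.55, adjusted p 1.8e-09). The linker histone gene HIST1H1A rose by 4.03 and LGALS3BP, which codes for a secreted galectin ligand, by 3.39. Of 23 cancer-testis antigens 18 rose and 1 fell (18 and 2 adjusted over the list alone; median 1.25, adjusted p 0.00024), including MAGEC2 (2.21). PAGE5 went from 0.0104 ± 0.015 to 2.73 ± 0.2 RPKM (SD, n = 2). Of 16 germ-cell genes 13 rose and 1 fell (13 and 1 adjusted over the list alone; median 0.77), among them TDRD12 (0.82), and DAZL was listed at 0 in DPBS. Of 38 interferon-stimulated genes 27 rose and 0 fell (27 and 0 adjusted over the list alone; median 0.40, adjusted p 0.00026), including ISG15 (1.99), IFI6 (1.89) and IFITM3 (2.68). MHC class I genes (15 rose and 0 fell of 18, 15 and 0 adjusted over the list alone; median 0.39), innate RNA-sensing genes (12 and 0 of 19, 13 and 0 adjusted over the list alone; 0.33), with the interferon regulator IRF7 at 1.73, and HOX genes (24 and 4 of 34, 24 and 6 adjusted over the list alone; 0.43), with HOXB5 at 1.90, were called higher. So were tumour suppressors silenced in liver cancer (19 and 1 of 34, 19 and 1 adjusted over the list alone; 0.19), with the Wnt antagonist gene SFRP4 at 1.48, and chemokines (10 and 0 of 25, 10 and 0 adjusted over the list alone; 0.12), with CXCL14 at 1.31. Proliferation genes (2 and 29 of 32, 2 and 29 adjusted over the list alone; -0.22), cholesterol genes (2 and 13 of 24, 2 and 13 adjusted over the list alone; -0.13) and ribosomal protein genes (0 and 69 of 76, 0 and 71 adjusted over the list alone; -0.32) were called lower. MT2A fell by 1.34. In all 7521 genes were called, 60.4% of them higher, or 49.1% after quantile normalization. Without scaling, the HOX, RNA-sensing, MHC class I, tumour suppressor, proliferation, cholesterol and ribosomal calls were lost. Their medians were then 0.43, 0.32, 0.41, 0.20, -0.24, -0.15 and -0.34. The HOX call was also lost with a pseudocount of 0.1 or the replicate letter in the model, and the chemokine call after quantile normalization, with the replicate letter and without decitabine library A (adjusted p 0.055).

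GSK-126 alone in SNU398 gave a stress response that was not called with decitabine or the combination. Scaling shifted the changes of all genes by a median of 0.14 in this comparison. The 2 GSK-126 libraries of this line had 60.9% and 57.2% of reads in genes, against 62.7% to 63.6% in its other libraries, and 12 of 13 mitochondrially encoded mRNAs were lower (0 higher and 12 lower adjusted over the list alone; median -0.65, adjusted p 0.18, not called as a list). GSK-126 made 410 genes at least 2-fold higher and 201 lower (403 and 195 also in the 8 SNU398 libraries alone, low-value ranges 264 to 1491 and 146 to 525). The collagenase gene MMP1 (ENSG00000196611, chromosome 11, 102660651 to 102668891) rose from 0.718 ± 0.016 to 29.5 ± 0.41 RPKM (SD, n = 2; log2 change 4.62, adjusted p 1.3e-16), and the stress cytokine gene GDF15 (ENSG00000130513, chromosome 19, 18485541 to 18499986) from 1.67 ± 0.082 to 49.2 ± 1.7 RPKM (SD, n = 2; 4.52). The early-response transcription factor gene FOS rose by 3.74, the neuropeptide precursor gene TAC1 by 3.38 and the lysosomal gene LAMP3 by 3.24. Of 22 unfolded-protein and integrated stress response genes 18 rose and 4 fell (18 and 4 adjusted over the list alone; median 1.13, adjusted p 0.0085), including SESN2 (3.06), TRIB3 (1.92) and the chaperone gene HSPA5 (1.54). The death receptor gene TNFRSF10B rose by 2.05, CDKN2B by 2.21 and HOXB9 by 2.43. Of 32 proliferation genes 0 rose and 31 fell (0 and 31 adjusted over the list alone; median -0.84, adjusted p 8.2e-05), including the mitotic kinesin gene KIF20A (-1.37). Of 71 histone genes 1 rose and 57 fell (1 and 58 adjusted over the list alone; median -0.89, adjusted p 0.012), with HIST3H2BB at -2.32, and of 24 cholesterol genes 0 rose and 21 fell (0 and 22 adjusted over the list alone; median -0.41). Cancer-testis antigens had a median of 0.03. In all 10147 genes were called, 57.3% of them higher, or 38.3% without scaling. There the stress-response and histone calls were lost, at medians of 0.97 and -1.06 (camera, adjusted p 0.095 and 0.071).

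The combination in SNU398 shared leading genes such as MYL9, LGALS3BP and IFITM3 with decitabine, both set against the same DPBS libraries. Both drugs made 309 genes at least 2-fold higher and 17 lower (305 and 15 also in the 8 SNU398 libraries alone, low-value ranges 158 to 1873 and 8 to 130); the latter count was 76 without DPBS library A, 33 without DPBS library B and 32 without combination library A. Of the 309, 157 were called above decitabine, 117 of them above both single treatments, 139 did not differ from decitabine and 13 were below it. MYL9 was at 14.4 ± 1.3 RPKM (SD, n = 2; log2 change 4.42), LGALS3BP rose by 3.29 and IFITM3 by 2.45. Of 23 cancer-testis antigens 19 rose and 2 fell (19 and 2 adjusted over the list alone; median 1.44, adjusted p 0.00053), including MAGEC2 (2.52). Germ-cell genes (13 and 1 of 16, 14 and 1 adjusted over the list alone; 0.72), interferon-stimulated genes (27 and 0 of 38, 28 and 0 adjusted over the list alone; 0.29), MHC class I genes (16 and 0 of 18, 16 and 0 adjusted over the list alone; 0.50), RNA-sensing genes (13 and 2 of 19, 13 and 2 adjusted over the list alone; 0.34), chemokines (11 and 0 of 25, 11 and 0 adjusted over the list alone; 0.14) and tumour suppressors (24 and 1 of 34, 24 and 1 adjusted over the list alone; 0.36) were called higher, the last with SFRP4 at 2.02 and TFPI2, an inhibitor of tissue factor, at 1.88. Proliferation (2 and 26, 2 and 27 adjusted over the list alone; -0.28), cholesterol (2 and 13, 2 and 13 adjusted over the list alone; -0.15) and ribosomal protein genes (0 and 73, 0 and 73 adjusted over the list alone; -0.37) were called lower. Without scaling, the MHC class I, RNA-sensing, tumour suppressor, proliferation, cholesterol and ribosomal calls were lost. Their medians were then 0.50, 0.31, 0.37, -0.31, -0.18 and -0.41. The chemokine call was lost after quantile normalization. In all 9165 genes were called, 61% of them higher, or 49.2% after quantile normalization. Against decitabine, 14 genes were at least 2-fold higher, among them the growth factor gene KITLG (1.3), the matrix protein gene SPP1 (1.25) and MT2A (1.23), and 8 were lower. In all 3976 genes differed from decitabine, or 2545 without decitabine library B and 2639 without combination library B. The interaction was at least 2-fold positive for 189 genes and negative for 384 (low-value ranges 135 to 497 and 255 to 1081), of which 368 had risen with GSK-126 alone and 213 with decitabine alone, such as MMP1 (-3.89), GDF15 (-3.76), FOS (-3.52) and SESN2 (-3.07). As a list, stress-response genes had a median interaction of -1.23 (3 positive and 17 negative, 4 and 17 adjusted over the list alone; adjusted p 0.003), interferon-stimulated genes -0.20 and MHC class I genes -0.33, while proliferation genes had 0.85, cholesterol genes 0.45 and histone genes 0.79. Scaling shifted the interactions of all genes by a median of -0.13. Those of the stress-response, interferon, MHC class I and histone lists were lost without scaling, where the share of positive calls went from 44.7% to 64.7%. That of the MHC class I list was also lost in 3 other settings and without any 1 DPBS or decitabine library (adjusted p 0.05 to 0.055). Among the 309 genes the interaction was positive for 47 and negative for 118.

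In SNU475, decitabine raised interferon and antigen-presentation genes. At least 2-fold higher were 312 genes and lower were 174 (310 and 167 also in the 8 SNU475 libraries alone, low-value ranges 214 to 895 and 96 to 775). The natriuretic peptide gene NPPB (ENSG00000120937, chromosome 1, 11917521 to 11918988) rose from 1.52 ± 0.16 to 40.1 ± 0.77 RPKM (SD, n = 2; log2 change 4.33, adjusted p 1.1e-14). The embryonic myosin gene MYH3 rose by 3.43 and the actin-capping gene CAPG by 3.27. Of 38 interferon-stimulated genes 33 rose and 3 fell (34 and 3 adjusted over the list alone; median 0.89, adjusted p 8.2e-05), including IFI27 (3.56) and the guanylate-binding protein gene GBP1 (ENSG00000117228, chromosome 1, 89518002 to 89531043), from 8.07 ± 0.01 to 77.8 ± 1.4 RPKM (SD, n = 2; 3.19). Of 18 MHC class I genes 15 rose and 0 fell (15 and 0 adjusted over the list alone; median 0.99, adjusted p 0.0019), including the peptide transporter gene TAP1 (2.17). Of 23 cancer-testis antigens 16 rose and 1 fell (17 and 1 adjusted over the list alone; median 0.47, adjusted p 0.0022), including MAGEA4 (2.91). Of 32 proliferation genes 30 rose and 1 fell (30 and 1 adjusted over the list alone; median 0.54), including the survivin gene BIRC5 (0.85), and of 24 cholesterol genes 1 rose and 18 fell (1 and 18 adjusted over the list alone; median -0.49), with the sterol sensor gene INSIG1 at -1.54. The fibrinogen chain genes FGB (-3.58), FGA (-2.77) and FGG (-2.57), hepatocyte products, had some of the largest falls, although FGA and FGG differed between DPBS replicates (6.98 ± 1.9 and 5.09 ± 1.7 RPKM; SD, n = 2) and a list of 14 fibrinogen and acute-phase genes, added after the data were seen, was not called (4 higher and 4 lower, 4 and 4 adjusted over the list alone; adjusted p 0.99). Without scaling, the MHC class I and proliferation calls were lost, at medians of 0.96 and 0.51 (camera, adjusted p 0.062 and 0.054). In all 9967 genes were called, 47% of them higher.

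GSK-126 alone in SNU475 also raised interferon-stimulated genes, in a comparison with the same 2 DPBS libraries, so a shift of those libraries would appear under every treatment. The GSK-126 libraries of this line had 65.7% and 66.7% of reads in genes, against 69.0% to 69.5% in its other libraries. At least 2-fold higher were 221 genes and lower were 192 (216 and 187 also in the 8 SNU475 libraries alone, low-value ranges 150 to 766 and 114 to 865). The MHC class II gene HLA-DRA (ENSG00000204287, chromosome 6, 32407619 to 32412823) rose from 0.107 ± 0.047 to 7.38 ± 0.3 RPKM (SD, n = 2; log2 change 3.70, adjusted p 3.5e-13), GBP4 by 3.52, GBP1 by 3.25, the chemokine gene CXCL14 by 2.98 and NPPB by 2.71. Of 38 interferon-stimulated genes 32 rose and 2 fell (33 and 2 adjusted over the list alone; median 0.99, adjusted p 8.2e-05), and of 18 MHC class I genes 15 rose and 2 fell (15 and 2 adjusted over the list alone; median 1.14, adjusted p 0.0011), including TAP1 (2.25). All 32 proliferation genes rose (32 and 0 adjusted over the list alone; median 0.56, adjusted p 8.2e-05), including PLK1 (0.96), and of 24 cholesterol genes 2 rose and 18 fell (2 and 19 adjusted over the list alone; median -0.36), a call lost without scaling. FGB (-3.56), the matrix metalloprotease gene MMP7 (-3.04), the adhesion molecule gene VCAM1 (-2.82) and the E-cadherin gene CDH1 (-2.25) fell. In all 9693 genes were called, 43% of them higher.

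The combination in SNU475 raised 380 genes at least 2-fold and lowered 340 (377 and 335 also in the 8 SNU475 libraries alone, low-value ranges 238 to 1081 and 200 to 1124). Of the 380, 189 were called above decitabine, 146 of them above both single treatments, 171 did not differ from decitabine and 20 were below it. NPPB rose by 4.59, the cardiac actin gene ACTC1 by 3.99, MYH3 by 3.89, IFI27 by 3.85 and MAGEA4 by 3.36. H19 went from 0.931 ± 0.16 to 69.5 ± 1 RPKM (SD, n = 2; log2 change 5.62), with 17.8 ± 0.06 in decitabine and 4.47 ± 0.27 in GSK-126. Interferon-stimulated genes (33 and 3 of 38, 34 and 3 adjusted over the list alone; 0.88), MHC class I genes (14 and 1 of 18, 14 and 1 adjusted over the list alone; 1.0), proliferation genes (30 and 1 of 32, 30 and 1 adjusted over the list alone; 0.63), histone genes (56 and 1 of 71, 56 and 1 adjusted over the list alone; 0.68), cancer-testis antigens (15 and 1 of 23, 15 and 1 adjusted over the list alone; 0.59) and germ-cell genes (11 and 2 of 16, 11 and 2 adjusted over the list alone; 0.28) were called higher. Cholesterol genes were called lower (2 and 19 of 24, 3 and 20 adjusted over the list alone; -0.50). The MHC class I, proliferation, histone and cholesterol calls were lost without scaling, at medians of 0.98, 0.61, 0.66 and -0.52 (camera, adjusted p 0.059 to 0.072). FGB (-4.08), the tetraspanin-like TM4SF4 (-3.26), MMP7 (-3.06) and the progenitor marker PROM1 (-1.44) fell. In all 10636 genes were called, 46.1% of them higher. Against decitabine, 14 genes were at least 2-fold higher, including H19 (1.94) and the stromelysin gene MMP3 (1.29), and 27 were lower, including TM4SF4 (-1.43) and PROM1 (-1.29). In all 3539 genes differed from decitabine, or 2281 without decitabine library A. The interaction was at least 2-fold positive for 130 genes and negative for 224 (low-value ranges 66 to 551 and 139 to 545). Interferon-stimulated genes (median -1.01, 2 positive and 30 negative, 2 and 31 adjusted over the list alone; adjusted p 8.2e-05), MHC class I genes (-1.08) and proliferation genes (-0.48) lay below the product of both effects. A low level in the shared DPBS libraries would also give negative values. As 1 member, GBP1 was at 77.8 ± 1.4, 81 ± 0.58 and 88.1 ± 1.2 RPKM in decitabine, GSK-126 and the combination (SD, n = 2). Cholesterol genes (0.36) and germ-cell genes (0.17) lay above it, calls lost without scaling, and the germ-cell call also after quantile normalization, with a pseudocount of 1 and without decitabine A, DPBS B, GSK-126 B or combination B (adjusted p 0.051 to 0.056). Among the 380 genes the interaction was positive for 66 and negative for 184.

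**Figure D2:**
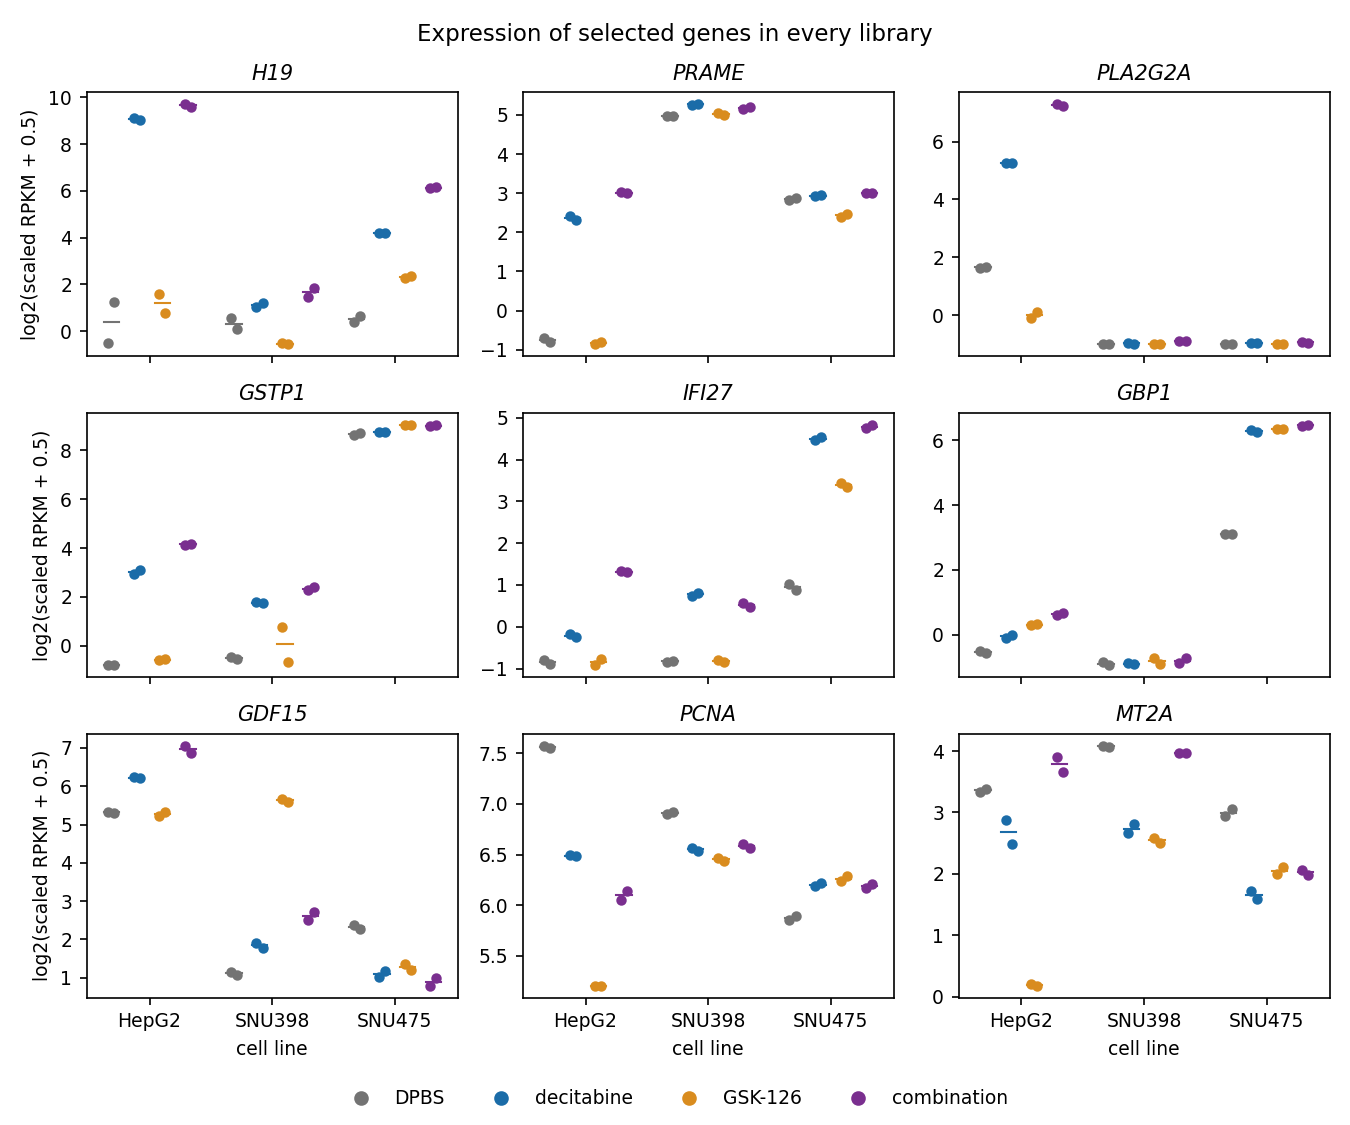
Expression of 9 genes as log2 of scaled RPKM plus 0.5 (y axis) in every library (points, n = 2 per group, with the mean as a line), by cell line (x axis) and treatment (colour). MT2A was lowest with GSK-126 alone in HepG2, at 0.643 ± 0.019 RPKM, and was at 13.3 ± 1.6 RPKM with both drugs.

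**Figure D3:**
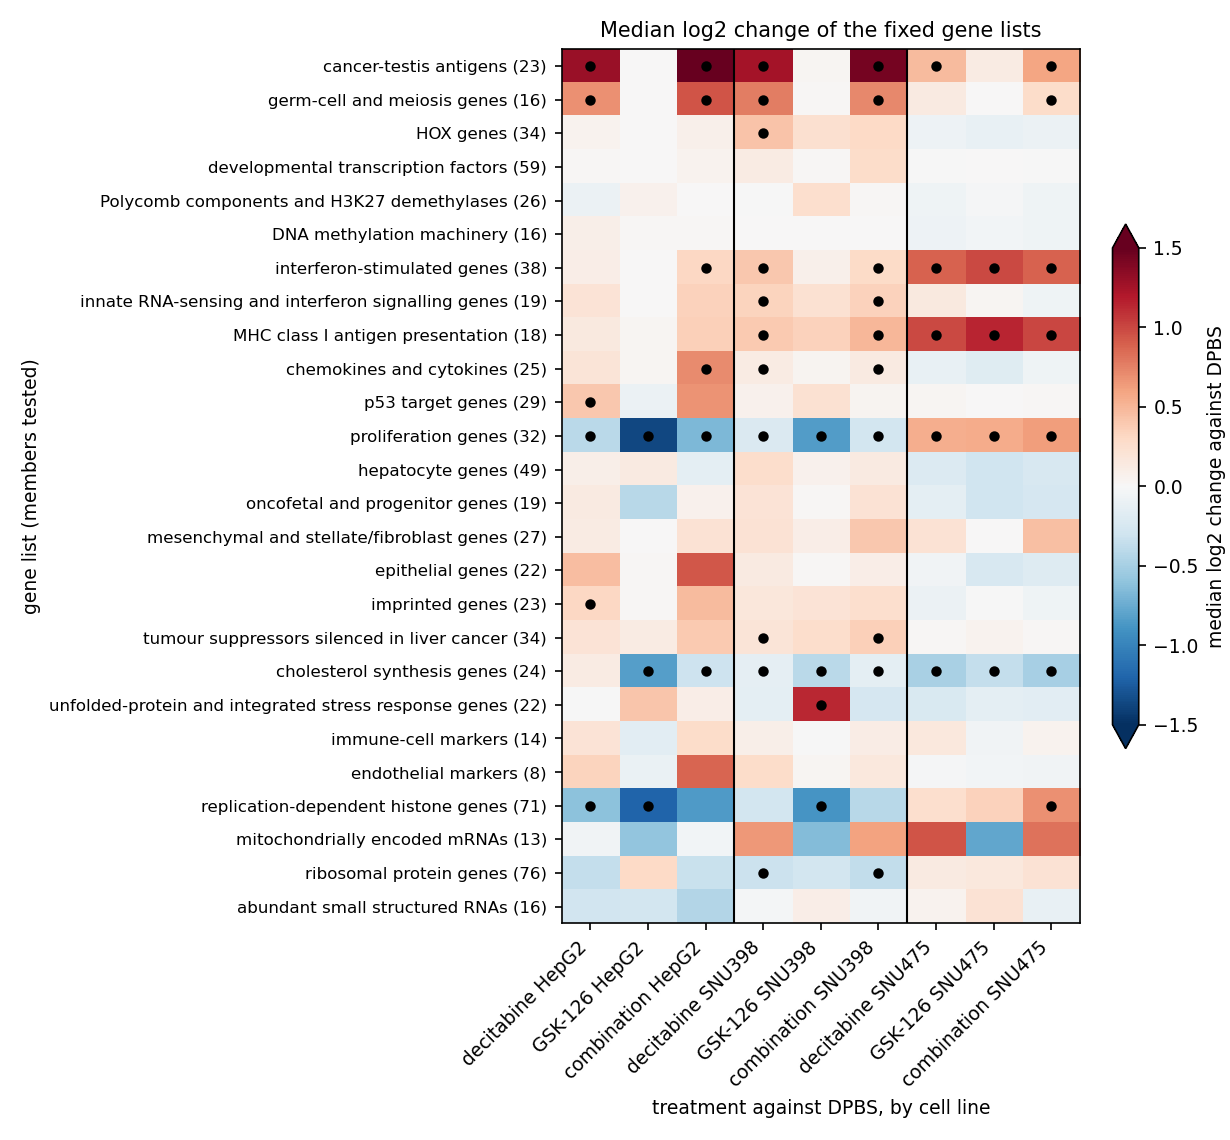
Median log2 change against DPBS (colour) of 26 gene lists (y axis, with the number of members tested) in 9 comparisons (x axis); dots mark the lists called by camera at adjusted p under 0.05. Cancer-testis antigens ranged from 0.47 to 2.17 with decitabine or the combination and were at or under 0.12 with GSK-126 alone; without scaling 38 of the 72 calls over comparisons with DPBS and interactions were lost, and after quantile normalization the uncalled medians of HOX (0.05), interferon-stimulated (0.10) and mitochondrial genes (-0.05) with decitabine in HepG2, among others, changed sign.

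Some genes responded alike in every line. At least 2-fold higher in all 3 lines were 20 genes with decitabine (0.1 expected if lines were independent) and 33 with the combination (0.4 expected). They included the X-linked cancer-testis antigens PAGE2 and PAGE5, the calcium-binding protein gene S100A4 (decitabine changes of 2.04 in HepG2, 1.55 in SNU398 and 1.82 in SNU475), CAPG (1.24, 2.25 and 3.27), ANKRD1 (1.73, 2.24 and 2.97) and the matricellular gene THBS1 (1.26, 1.15 and 2.22). With GSK-126 limma called 0 genes at least 2-fold higher in all 3 lines (0 at an unadjusted p under 0.05), against 5 with a pseudocount of 0.1 and 20 with voom, and 2 at least 2-fold lower. At any size 630 genes rose in all 3 lines with GSK-126 (387.4 expected), including CYR61 (2.54, 2.53 and 0.98), the non-classical HLA gene HLA-E (0.87, 1.01 and 0.87) and IRF1 (0.69, 0.64 and 1.60). The sterol enzyme gene MSMO1 (-1.56, -1.17 and -0.96), MT2A (-3.17, -1.54 and -0.94) and the aldolase gene ALDOC (-2.80, -0.91 and -2.29) were among 547 that fell with GSK-126 (267.3 expected). With the combination 1256 rose (573.8 expected) and 616 fell (274.3 expected), the latter including the DNA demethylase gene TET1 (-0.90, -0.55 and -1.07) and the cell-cycle inhibitor gene CDKN1B (-0.76, -0.50 and -1.10).

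The lines differed in how strongly they responded to the combination. The difference in effect was called for 11254 genes between SNU398 and HepG2, 12527 between SNU475 and HepG2 and 10946 between SNU475 and SNU398. Cancer-testis antigens responded less than in HepG2, with median differences of -0.91 in SNU398 (0 above and 18 below, 0 and 18 adjusted over the list alone; adjusted p 0.0026) and -1.32 in SNU475 (2 and 17, 3 and 17 adjusted over the list alone; adjusted p 0.0076). Proliferation genes responded more positively in SNU475 than in HepG2, by 1.28 (32 and 0, 32 and 0 adjusted over the list alone; adjusted p 0.00012). The share of differences that were positive between SNU475 and HepG2 was 38.4%, or 50.6% after quantile normalization. SNU475 was harvested 7 days later than the other lines, so line and harvest day were one contrast.

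**Figure D4:**
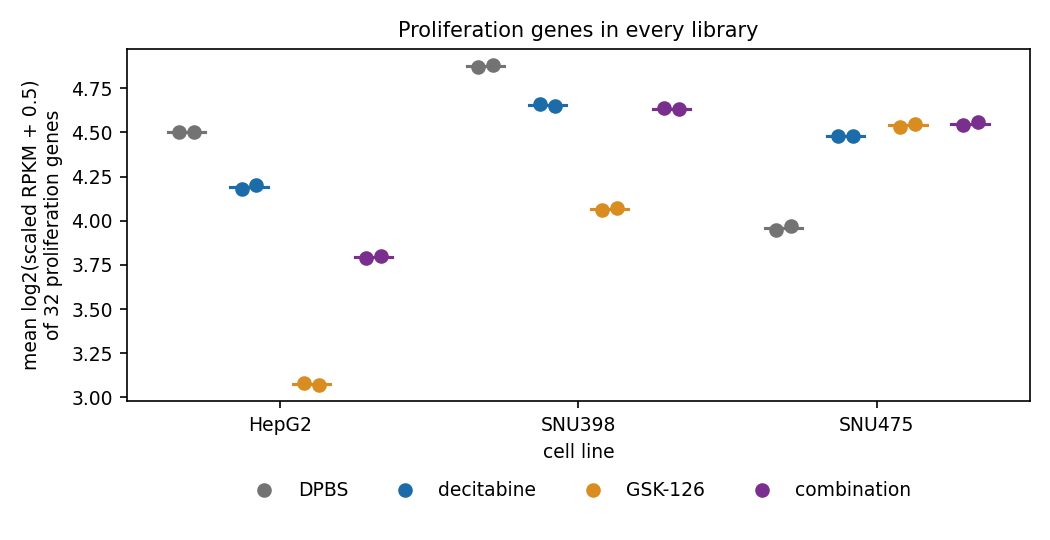
Mean log2 of scaled RPKM plus 0.5 over 32 proliferation genes (y axis) in each library (points, n = 2 per group, with the mean as a line), by cell line (x axis) and treatment (colour). In HepG2 the DPBS libraries were at 4.50 and the GSK-126 libraries at 3.07 and 3.08, while in SNU475 the DPBS libraries were at 3.95 and 3.97 and all treated libraries between 4.48 and 4.56.

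The mRNAs of EZH2, DNMT1, DNMT3A and DNMT3B changed by less than 2-fold in the comparisons with DPBS, except DNMT3B with GSK-126 in SNU398. EZH2 (ENSG00000106462, chromosome 7, 148504475 to 148581413), the methyltransferase that GSK-126 inhibits, was at 8.59 ± 0.3 RPKM in HepG2 DPBS (SD, n = 2) and changed by -0.47, -0.88 and -0.71 with decitabine, GSK-126 and the combination, by -0.21, 0.32 and -0.21 in SNU398 and by 0.25, 0.51 and 0.44 in SNU475. DNMT1 (ENSG00000130816, chromosome 19, 10244021 to 10341962), the maintenance DNA methyltransferase that decitabine depletes as a protein, changed by -0.14, -0.77 and -0.24 in HepG2, -0.11, -0.55 and -0.13 in SNU398 and 0.22, 0.27 and 0.28 in SNU475. Its partner UHRF1 fell most with GSK-126 in HepG2 (-1.71) and SNU398 (-0.86) and rose in SNU475 (0.66). DNMT3B fell with GSK-126 in all 3 lines (-0.53, -1.04 and -0.40) and rose with decitabine (0.81, 0.16 and 0.15), where the calls in SNU398 and SNU475 were each lost without either of 2 libraries (DPBS B or decitabine B, and decitabine A or DPBS B; adjusted p 0.054 to 0.1), and that in SNU475 without scaling. DNMT3A rose with decitabine in HepG2 (0.35) and SNU398 (0.25). The Polycomb core genes EED and SUZ12 changed by -0.45 and -0.75 with the combination in HepG2.

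Lists of cell identity were not called in any comparison with DPBS. These were hepatocyte genes (medians from -0.30 to 0.26), oncofetal and progenitor genes (-0.42 to 0.22), mesenchymal and stellate/fibroblast genes (lowest adjusted p 0.08, with the combination in SNU475, where 19 of 27 rose and 5 fell, 19 and 5 adjusted over the list alone), epithelial genes (0.11, combination in HepG2, 20 and 1 of 22, 20 and 1 adjusted over the list alone, median 0.93), immune-cell markers (0.13) and endothelial markers (0.13, combination in HepG2, 6 and 0 of 8, 6 and 0 adjusted over the list alone, median 0.87). Developmental transcription factors (0.16), Polycomb components and H3K27 demethylases (0.23), DNA methylation machinery (0.5) and abundant small structured RNAs (0.17) were not called either. The 13 mitochondrially encoded mRNAs were not called (lowest adjusted p 0.13), with 13 higher and 0 lower with decitabine in SNU475 (13 and 0 adjusted over the list alone; median 0.94) and a median of -0.78 with GSK-126 there. Under quantile normalization these medians were 0.28 and -0.69. Members listed at 0 in DPBS make a list's median depend on the pseudocount. With these members held at a floor of 3 reads over the DPBS group, the cancer-testis medians were 1.60 and 2.81 in HepG2 (decitabine and combination; 7 members at 0), 1.67 and 1.85 in SNU398 (4 at 0) and 0.47 and 0.59 in SNU475 (1 at 0). Germ-cell medians were 0.96 and 1.12 in HepG2, 1.09 and 1.12 in SNU398 and 0.37 with the combination in SNU475. With the preset correlation of 0.01 in place of the estimated one, 146 list tests were called, including all 72.

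Repeat elements were summed per subfamily because both drugs remove marks that silence endogenous retroviruses. In HepG2, decitabine raised 717 of 843 subfamilies and lowered 32 (484 and 19 of 585 over loci outside gene bodies). With reads scaled over the subfamilies themselves, 257 rose and 253 fell, so the count describes a joint rise of the repeat share. In the same libraries the reads in 379 olfactory receptor genes, normally expressed in olfactory neurons, went from 62 to 145, with a gain in RPKM of 0.60 times that of repeats outside gene bodies. LTR12/HERV9 elements, a primate retrovirus family whose long terminal repeats act as promoters, rose too: 7 of 8 subfamilies were higher with decitabine (median 1.0, or 1.49 outside gene bodies) and 8 with the combination (1.17, or 1.72). LTR12_ went from 3.67 ± 0.34 to 18.3 ± 0.012 RPM with decitabine (SD, n = 2; log2 change 2.17) and to 29.2 ± 0.49 RPM with both drugs (2.83, or 2.58 outside gene bodies). Its top locus lay in a gene body on chromosome 14 from 74034039 to 74034767 and held 14.3% of the subfamily's reads in the combination. HERVH-int rose with decitabine by 2.0 (2.63 outside gene bodies). SVA elements rose with decitabine (median 1.04) and the combination (1.64). L1 elements rose with decitabine (114 of 116, median 0.92) and fell when GSK-126 was added (114 lower than with decitabine alone, median -1.20), as did most subfamilies (37 higher and 685 lower of 843, median -0.58). Over all subfamilies the combination against DPBS gave 308 higher and 296 lower, or 255 and 135 of 585 over loci outside gene bodies. GSK-126 alone gave 612 higher and 53 lower, or 205 and 209 when scaled over the subfamilies.

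In SNU398, 93 subfamilies rose with decitabine and 32 fell. The 125 called were 46 without DPBS library A, 64 without decitabine library A and 67 without decitabine library B. With the combination 415 rose and 29 fell, or 119 and 115 when scaled over the subfamilies. HERV9-int rose from 10.1 ± 0.46 to 39.3 ± 0.026 RPM with both drugs (SD, n = 2; log2 change 1.91, or 1.06 outside gene bodies), LTR12D by 1.79 (1.31) and the pericentromeric satellite HSATII by 1.58 (1.56). GSK-126 gave 109 higher and 193 lower, which turned to 292 and 78 with the scaling factors of the gene table and to 103 and 50 outside gene bodies. In SNU475 most called subfamilies fell: 40 rose and 581 fell with decitabine, 38 and 442 with GSK-126 and 46 and 609 with the combination, splits that came to 226 and 155, 136 and 140, and 238 and 189 when reads were scaled over the subfamilies. LTR39 rose there from 7.1 ± 0.046 to 23.3 ± 0.12 RPM with the combination (SD, n = 2; 1.64), and 79.9% of its reads came from 1 locus outside gene bodies on chromosome 18 from 516070 to 516818, which was at 0.526 ± 0.04 RPKM in DPBS and 24.8 ± 0.044 with both drugs (SD, n = 2).

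**Figure D5:**
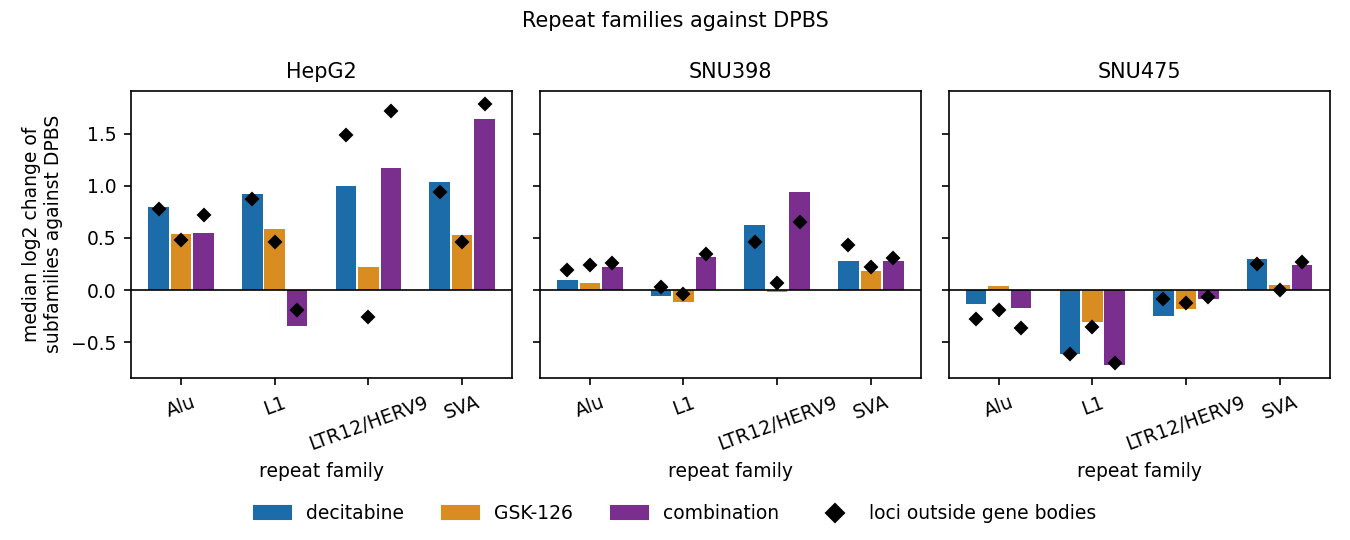
Median log2 change against DPBS (y axis) of the subfamilies of 4 repeat families (x axis) in each cell line, by treatment (bar colour), with diamonds for loci outside gene bodies. LTR12/HERV9 medians were 1.0 with decitabine and 1.17 with the combination in HepG2, and the split of all called subfamilies with GSK-126 in SNU398 changed direction with the scaling.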

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

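The tests of swapped labels, of the state of the GSK-126 dishes, of reads from introns, of library scaling factors for repeats, of DPBS libraries standing apart and of the later harvest, and the gains of olfactory receptor genes in other comparisons, were chosen only after the result was seen.

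The first results in this part drew attention because an interaction test found that the effect of the combination differed between cell lines. The patterns of GSK-126 alone and of repeats with decitabine, given further below, were not picked by that test. The difference was called for 11254 genes between SNU398 and HepG2, 12527 between SNU475 and HepG2 and 10946 between SNU475 and SNU398. Cancer-testis antigens differed by a median of -0.91 between SNU398 and HepG2 (adjusted p 0.0026) and -1.32 between SNU475 and HepG2 (0.0076). Interferon-stimulated genes differed by 0.40 between SNU475 and HepG2 (0.0076) and 0.45 between SNU475 and SNU398 (0.0035). MHC class I genes differed by 0.56 (0.02) and 0.39 (0.042) in those comparisons, and replication-dependent histone genes by 1.32 (0.042) and 1.05 (0.041). Proliferation genes differed by 0.48 between SNU398 and HepG2 (0.0035), 1.28 between SNU475 and HepG2 (0.00012) and 0.86 between SNU475 and SNU398 (0.00012).

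In HepG2 and SNU398, proliferation genes fell further with GSK-126 alone (medians -1.37 and -0.84) than with the combination (-0.67 and -0.28). A swap of GSK-126 and combination libraries would have raised cancer-testis antigens in the libraries labelled GSK-126, where the highest median over the lines was 0.12. Scaling was argued against, since the median nearest to 0 over both lines and 2 other scalings was -0.83. What stays open is the state of the GSK-126 dishes apart from the drug: across genes, which are not independent replicates, the effect of GSK-126 alone and on top of decitabine had a correlation of 0.10 in HepG2, 0.19 in SNU398 and 0.30 in SNU475. A protection by decitabine and a difference between dishes, such as density or medium, cannot be told apart, because each treatment was given to its own dishes.

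Repeat subfamilies rose together with decitabine in HepG2 (717 of 843). Introns as the only source were argued against by the median over loci outside gene bodies, 0.71. With the factors of the gene table, 96.8% of called subfamilies were higher. This could not test scaling as an explanation. The repeat sums were unscaled, and these factors were lower with decitabine (0.849 and 0.847) than with DPBS (0.901 and 0.912). Dividing by them therefore raises decitabine further. Scaled over the subfamilies themselves, 257 rose and 253 fell, but that scaling takes out a joint rise by construction. Most repeat reads still lay in gene bodies. Repeats summed here went from 2.76% and 2.84% of reads to 4.50% and 4.49%. Those outside gene bodies went from 0.36% and 0.37% to 0.67% and 0.66%. How much of the rise came from introns was not tested. Genomic DNA in these libraries stays open as a candidate explanation: olfactory receptor genes gained 0.60 of the RPKM that repeats outside gene bodies gained (95% counting interval 0.42 to 0.78), from 62 to 145 reads. Part of that gain lay in few genes, with OR2F1 at 23 against 7 reads, OR2B6 at 17 against 1 and OR52N4 at 12 against 3, and activation of these genes by loss of methylation was not tested apart. With GSK-126 in HepG2, where 612 subfamilies were higher, olfactory receptor genes gained 0.00111 RPKM and repeats 0.00158. These genes also gained where repeats gained less or fell: in RPKM by 0.00328 with the combination in HepG2 (repeats 0.00192, against 0.00247 and 0.00412 with decitabine), 0.0042 with GSK-126 in SNU398 (0.000206) and 0.00298 with the combination in SNU475 (-0.00179). Their gain therefore went with the joint rise in HepG2 but was also seen without it, and the explanation was neither shown nor excluded.

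Proliferation genes rose with every treatment in SNU475 and fell in the other lines. Scaling was argued against by the lowest median with the combination in SNU475 over 2 other scalings, 0.56. Without scaling, however, camera no longer called the list with decitabine (median 0.51, adjusted p 0.054) or the combination (0.61, 0.059). The treated groups of SNU475 differed from each other by a median of at most 0.07, as they would if its DPBS libraries, at 3.95 and 3.97 against 4.48 to 4.56, were the ones apart, so a DPBS culture that had slowed may account for the direction. The interferon-stimulated genes of SNU475, with medians of 0.89, 0.99 and 0.88 against the same DPBS libraries, are open to a shift of these libraries too. The number of SNU475 libraries harvested on the day of the other lines was 0, so the later harvest and a property of the line cannot be told apart.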

How the results depend on the processing

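The settings added only after the result was seen were voom on recovered reads, repeat loci outside gene bodies, and, for gene lists, quantile normalization, a pseudocount of 1 and medians with a floor of 3 reads.

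Counts of genes and subfamilies stayed within 1.5 times under 452 of 570 combinations of a result and another setting, and under 518 of 528 that left out 1 library, where the lone library of a group was assumed to vary like the other groups. With the replicate letter in the model, 12817 genes were called for the combination in HepG2, 9114 in SNU398 and 10595 in SNU475, and 69 list tests. Over 534 pairs of a list call and another setting, the list was no longer called in 61, 40 of them without scaling, and over 712 pairs with 1 library left out in 21, and 0 reversed (camera). Of the genes named, 2 calls were lost and 1 was gained in another setting and 4 lost and 2 gained without 1 library, against 1851 and 1642 unchanged. In the following the cause was not tested, except that a smaller or larger pseudocount widens or shrinks every change at low values by construction.

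With a pseudocount of 0.1 the following counts of genes changed at least 2-fold moved by more than 1.5 times. For decitabine they were HepG2 1504 higher and 202 lower, SNU398 616 higher and 41 lower, SNU475 625 higher and 441 lower. For GSK-126 they were HepG2 657 higher, SNU398 862 higher and 343 lower, SNU475 466 higher and 474 lower. For the combination they were HepG2 2437 higher and 842 lower, SNU398 869 higher and 79 lower, SNU475 717 higher and 826 lower. For the combination against decitabine they were HepG2 575 higher and 545 lower, SNU398 55 higher and 25 lower, SNU475 49 higher and 85 lower. For the interaction they were HepG2 1086 higher and 1192 lower, SNU398 344 higher and 733 lower, SNU475 366 higher and 409 lower. Genes at least 2-fold higher in all 3 lines were 67 with decitabine, 5 with GSK-126, 115 with the combination. Those at least 2-fold higher with the combination and above both single treatments were 1674 in HepG2 and 223 in SNU398.

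A pseudocount of 1 shrinks low values and moved these counts. For decitabine they were HepG2 280 higher, SNU398 112 higher and 7 lower, SNU475 96 lower. For GSK-126 they were HepG2 144 higher, SNU398 264 higher, SNU475 114 lower. For the combination they were HepG2 750 higher, SNU398 158 higher and 8 lower, SNU475 238 higher and 200 lower. For the combination against decitabine they were HepG2 103 higher and 104 lower, SNU398 6 higher and 3 lower, SNU475 4 higher and 10 lower. For the interaction they were HepG2 425 lower, SNU398 255 lower, SNU475 66 higher and 139 lower. Genes at least 2-fold higher in all 3 lines were 12 with decitabine, 16 with the combination. Those at least 2-fold higher with the combination and above both single treatments were 656 in HepG2 and 66 in SNU398.

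With voom on recovered reads, which has no pseudocount of 0.5 RPKM, these counts moved. For decitabine they were HepG2 2555 higher and 231 lower, SNU398 1360 higher and 84 lower, SNU475 895 higher and 775 lower. For GSK-126 they were HepG2 1135 higher and 818 lower, SNU398 1491 higher and 525 lower, SNU475 766 higher and 865 lower. For the combination they were HepG2 3635 higher and 898 lower, SNU398 1873 higher and 130 lower, SNU475 1081 higher and 1124 lower. For the combination against decitabine they were HepG2 1154 higher and 556 lower, SNU398 223 higher and 64 lower, SNU475 145 higher and 137 lower. For the interaction they were HepG2 1149 higher and 1350 lower, SNU398 497 higher and 1081 lower, SNU475 551 higher and 545 lower. Genes at least 2-fold higher in all 3 lines were 170 with decitabine, 20 with GSK-126, 282 with the combination. Those at least 2-fold higher with the combination and above both single treatments were 1939 in HepG2 and 333 in SNU398.

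Without scaling, 337 genes were at least 2-fold lower with GSK-126 in SNU398, 33 with the combination there, the interaction there was at least 2-fold positive for 327, and 34 list tests were called, against 146 with the preset correlation. With quantile normalization 410 genes were at least 2-fold higher with decitabine in HepG2, 33 lower with decitabine in SNU398 and 48 lower with the combination in SNU398. With a filter at 1 RPKM, 5 were at least 2-fold lower with the combination than with decitabine in SNU398. Of the genes called higher with the combination, 5010 of 7864 in HepG2, 1981 of 5592 in SNU398 and 1338 of 4899 in SNU475 lay above the sum of the single changes, counts in 1 direction with no test, which cannot be set against the interaction calls in both directions.

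Of repeat subfamilies, the median-of-ratios factors over subfamilies left 414 called with GSK-126 in HepG2, 234 with the combination in SNU398, and 381, 276 and 427 with decitabine, GSK-126 and the combination in SNU475. Loci outside gene bodies, which make fewer subfamilies, left 372 and 390 with GSK-126 and the combination in HepG2, 153 and 291 in SNU398, and 385 and 436 with decitabine and the combination in SNU475.

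Leaving out 1 library in turn gave 16 to 76 genes at least 2-fold lower with the combination in SNU398 (76 without DPBS A, 33 without DPBS B, 32 without combination A). For the combination against decitabine it gave 2545 to 3871 genes in SNU398 (2545 without decitabine B, 2639 without combination B), of which 8 to 13 were at least 2-fold lower (13 without decitabine B), and 2281 to 3448 in SNU475 (2281 without decitabine A). For repeats with decitabine in SNU398 it gave 46 to 125 (46 without DPBS A, 64 without decitabine A, 67 without decitabine B). Depth limits genes near 0: the denominators went down to 32.6 in units of 1e6 reads, and genes listed near 0 rest on few reads.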

Other observations

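The 6 gene lists in this part were chosen only after the result was seen, as were their tests.

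Hypoxia-responsive genes fell in HepG2 with each treatment: 2 of 29 rose and 26 fell with decitabine (median -0.99, adjusted p 6.3e-05), 2 and 25 with GSK-126 (-1.27, 9.2e-05) and 4 and 23 with the combination (-0.82, 0.0013). Their interaction there was 1.36 (24 positive and 2 negative, adjusted p 0.00022). The 3 comparisons share the same 2 DPBS libraries, and high values in these alone would give the same falls and a positive interaction, so they do not count as 3 separate drug effects. Members included the glycolytic regulator PFKFB4, with changes of -1.91, -2.95 and -2.31, and the aldolase gene ALDOC. In SNU475 they fell with GSK-126 (5 and 21, median -0.37, adjusted p 0.015), a call lost without scaling, and their interaction was 0.43 (20 positive and 4 negative, 0.004). Metallothionein genes, whose products bind zinc and copper, fell in HepG2 with decitabine (0 and 5 of 7, median -1.28, adjusted p 0.042) and GSK-126 (0 and 5, -2.15, 0.033). With the combination 3 rose and 4 fell (-1.04, adjusted p 0.43, not called). Their interaction was 2.22 (7 positive and 0 negative, 0.026), with MT1E at 4.03 and MT1X at 1.84. High values in the shared HepG2 DPBS libraries would here too give falls and a positive interaction. The decitabine call of this list was lost without scaling (adjusted p 0.065), with a pseudocount of 0.1 (0.085), with the replicate letter in the model (0.061), after quantile normalization (0.08) and without either GSK-126 library (0.05), and the GSK-126 call with the replicate letter (0.05).

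In SNU475 genes typical of interferon gamma were higher than in DPBS. Of 16 such genes 16 rose with decitabine, 15 with GSK-126 and 16 with the combination (medians 1.13, 1.54 and 1.37, each with an adjusted p of 6.3e-05), and the interaction was -1.49 (1 positive and 14 negative). MHC class II genes, normally expressed in antigen-presenting cells, had medians of 0.82, 1.64 and 1.34 (6, 5 and 6 of 6 rose, adjusted p 0.015, 0.0059 and 0.015) and an interaction of -1.31 (0 positive and 6 negative, 0.0044), led by HLA-DRA. All of these comparisons share the same SNU475 DPBS libraries. Low values in these libraries alone would give the same rises and a negative interaction for both lists. The rises therefore do not count as separate drug effects. Fibrinogen and acute-phase genes were called in no comparison (medians from -0.11 to 0.23 against DPBS), although FGB, FGA and FGG fell in SNU475, where DPBS replicates of FGA (6.98 ± 1.9 RPKM) and FGG (5.09 ± 1.7 RPKM) differed (SD, n = 2). snRNA and snoRNA genes were called in no comparison (434 genes, lowest adjusted p 0.093, with 32 higher and 92 lower for the combination in HepG2).

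Genes raised by decitabine were mostly higher again when it was added to GSK-126, unlike the genes it lowered in HepG2 and SNU398. Of the genes at least 2-fold higher with decitabine alone, 451 of 617 in HepG2 (227.4 expected if independent), 174 of 210 in SNU398 (55.9) and 218 of 312 in SNU475 (56.8) were also higher with the combination than with GSK-126. Of those at least 2-fold lower, 30 of 107 (30.8 expected), 1 of 21 (4.9) and 92 of 174 (30.8) were lower again, and 56, 5 and 10 were higher. For genes raised by GSK-126, then on top of decitabine, these were 88 of 247 (74.1 expected), 147 of 410 (51.1) and 97 of 221 (16.3). Of the genes it lowered, 275 of 449 (115.6 expected), 45 of 201 (16.2) and 89 of 192 (20.9) were lower again. The median change of the genes raised by GSK-126 went from 1.19 alone to 0.05 on top of decitabine in HepG2, from 1.26 to 0.09 in SNU398 and from 1.32 to 0.17 in SNU475, and that of the genes raised by decitabine from 1.32 to 1.29, 1.35 to 1.15 and 1.33 to 0.78. The first value of each pair is high by selection, and some shrinkage of the second follows from it.

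An element of the LTR10E subfamily outside gene bodies on chromosome 8 from 145148368 to 145148856 was at 11.6 ± 0.34 RPKM in HepG2 DPBS and 0.278 ± 0.069 with decitabine and 0.047 ± 0.066 with GSK-126 (SD, n = 2), and was listed at 0 with the combination, so it was high in the shared DPBS libraries and near 0 under each treatment. Over 18 pairs of groups, the difference between libraries A and B had a correlation across genes, which are not independent replicates, between -0.12 and 0.24, and the letters were not treated as pairs.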
